A study of Mus musculus with 12 samples.

How the data were processed

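Mouse embryonic fibroblasts with and without Sirt2 were compared untreated and after 4 h of mouse interferon beta at 2500 IU/ml, in 4 groups of 3 samples. Per the labels, biotinylated RNA made from 150 ng of total RNA was hybridised to single-colour Illumina bead arrays, and each sample has its own array. The authors deposited a table with 1 intensity per probe and array on a linear scale, neither background-subtracted nor scaled between arrays. Per the file headers, each intensity comes with a detection p-value, which compares the probe with the negative controls of the array. The scanner software is not given in the sources used here. A further deposited table holds log2 values, which were checked to equal the quantile-normalized log2 of the deposited intensities within 0.0012, so the authors subtracted no background.

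The intensities were background-corrected with the normexp model, with the mean and SD of the negative controls inferred from the detection p-values, an offset of 16 was added, and the values were quantile-normalized and log2-transformed (the neqc method of limma 3.58.1 in R 4.3.3). Of 45281 probes, 34885 carry 1 gene symbol, 18 several and 10378 none. For 34807 probes the symbol was looked up by gene ID in a RefSeq table, which changed 0 symbols. A probe was tested if its detection p was under 0.05 on all 3 arrays of at least 1 group, which kept 17837 probes. For each symbol the kept probe with the highest mean over the 12 arrays stood for the gene, and probes with no symbol stood for themselves: 12128 features, called genes here, of which 9723 have a name. A total of 3837 named genes had more than 1 kept probe. The probe of Ifit1 was detected on 4 arrays and was not kept, so this gene is not reported.

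A mean per group was fitted to the 12 arrays with limma and moderated by empirical Bayes, and 5 contrasts were tested two-sided: the interferon response in each genotype, the genotype difference with and without interferon, and the difference of the responses. Adjusted p-values are limma's, by the Benjamini-Hochberg method over 12128 genes, with a threshold of 0.05. Differences are log2 values with their standard error, and genotype differences are knockout minus wild type. Where a gene had a detection p of 0.05 or more on all 3 arrays of a group, its fold is given as a lower bound against the background level. The same holds for a group left with 1 array, where the gene was not detected on that array. The number of arrays limits the precision.

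Of 29 gene lists fixed before the data were examined, 28 had at least 3 tested members. They were tested with camera at a preset correlation between genes of 0.01, and beside it with an estimated correlation, adjusted over the lists of a contrast. Members were counted over all genes and adjusted over the list alone. The mean log2 value of the antiviral list on each array was compared between groups with an exact permutation test. The size of the responses was compared over genes called at least 2-fold higher for the mean of both responses, a mean that is independent of their difference only where all groups vary alike. The antiviral mean varied more in the untreated knockout group (SD 1.08) than in the untreated wild type (SD 0.18).

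The design, the lists, the alternatives and the rule for naming genes were fixed then too. The rule names, in each contrast, the 10 genes with the largest change in each direction among those past the threshold whose groups do not overlap (for the difference of the responses, among those past the threshold), the 3 members of each described list with the largest change past the threshold, and 16 genes always. Not all of them are printed. Genes outside the rule are named where the text says that they were chosen after their values were seen.

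After the values were seen, marker genes were chosen to measure transcripts of another group on each array. Wild-type-only genes had a mean log2 level between 9 and 12 in both wild-type groups, changed by less than 0.5 with interferon there, and had a mean under 6, and lower by over 3, in the treated knockout group. Knockout-only genes had a mean between 9 and 12 in the treated knockout group, a mean under 6 in both wild-type groups, lower by over 3 in the treated one, and changed by less than 1 in the wild-type response. Interferon-induced genes rose by over 3 in wild type from a mean under 6, and had means between 9 and 12 that differed by less than 1 in the treated groups. Their level on an array, on the linear scale, was counted from a reference array as 0 and given in percent of the arrays that express them. The reference was treated knockout array 1 for wild-type-only genes, untreated wild-type array 1 for knockout-only genes, and untreated array 1 of the genotype for interferon-induced genes. Each set was summarised by its median, with a 95% interval from 2000 bootstrap resamples of the genes. The measure was tested on simulated mixtures: 5% of treated wild-type array 1 mixed into untreated knockout array 1 gave 4.85% by wild-type-only and 5.31% by interferon-induced genes. For the splits of the arrays in the difference of the responses, the count was repeated with each gene's mean genotype difference subtracted.

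The fit and the calling of genes were tested on simulated log2 values with 200 changed genes of 12128. Background correction, scaling, the detection filter and the choice of probes were not part of this test. Each simulated gene had the same spread in all groups. The rates need not hold for the real arrays, where the untreated knockout group varied more and far more genes were called between genotypes. For the wild-type response, 44% of changes of 0.5, 98% of changes of 1 and 100% of changes of 2 were recovered, and 6.56% of 183 calls were false. For the difference of the responses, 8%, 84% and 100% were recovered, and 3.33% of 150 calls were false. The alternatives were other background corrections and scalings, the authors' deposited values, other detection filters, only the 6 arrays of a contrast, array weights, a replicate block, a minimum log2 change of 1, other tests of lists, leaving out each array in turn, and, chosen after the data were seen, leaving out the arrays with transcripts of another group. When untreated knockout arrays 2 and 3 were left out, the lone remaining array was assumed to vary like the other groups. With all arrays the antiviral mean varied most in that group (SD 1.08), so the assumption is weak. Adjusted p-values and counts that involve the lone array do not measure the spread of its group. No sample was left out of the values given without such a remark. Plots were drawn with matplotlib 3.10.9.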

Results

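The cells were mouse embryonic fibroblasts, connective tissue cells grown in culture, that carried the gene Sirt2 (wild type) or lacked it (knockout). Each genotype was measured untreated and after 4 h with mouse interferon beta, a type I interferon, at 2500 IU/ml. RNA was measured on 12 single-colour Illumina bead arrays, 3 in each of the 4 groups. Between 17091 and 18155 of 45281 probes were detected per array, and the median intensity per array lay between 111 and 119.9. Arrays of a group correlated with Pearson's r between 0.987 and 0.996 across probes, which are not independent replicates. In a principal component analysis, the first component held 63.3% of the variance and separated the genotypes, and the second held 25.4% and separated treated from untreated arrays. The labels do not say whether the 3 samples of a group are separate cultures or embryos, so the p-values measure only the spread between samples, which may be technical.

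Sirt2, which encodes a deacetylase found mostly in the cytoplasm, was lower in every knockout array than in every wild-type array. Its log2 intensity was 8.72, 8.89 and 8.94 in the untreated wild-type arrays and 9.22, 8.75 and 8.97 in the treated ones. In the knockout it was 6.04, 6.65 and 6.61 untreated and 5.85, 6.36 and 6.15 under interferon. The knockout value was lower by a log2 difference of −2.42 ± 0.18 (SE, n = 3 arrays per group, adjusted p = 2.37e-07) without interferon and of −2.86 ± 0.18 (adjusted p = 6.54e-08) with it. With the authors' deposited values, which have no background subtracted, these differences were −1.63 and −1.89. The probe was detected on all 6 knockout arrays, and whether it lies in the deleted part of the gene is not given in the sources used here.

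The 3 untreated knockout arrays were not alike. A set of 31 genes that were expressed in the wild-type arrays and near background in the treated knockout group was chosen without any untreated knockout array, and includes Xist, Dcn, Vip, Gpr149 and Hoxc9, named here after their values were seen. In untreated knockout array 1 these genes stood at a median of −0.0511% of their wild-type level, counted from treated knockout array 1. They stood at 6.16% (95% bootstrap interval 4.36 to 8.02) in array 2 and at 4.35% (3.66 to 4.91) in array 3, where 30 and 31 of them were detected against 6 in array 1. A set of 25 interferon-induced genes stood in arrays 2 and 3 at 9.80% and 16.2% of the level of treated cells, counted from array 1. Treated knockout arrays 2 and 3 held the wild-type-only genes at 1.33% and 1.38%, and treated wild-type array 2 held 7 knockout-only genes at a median of 2.65%. Values that move with untreated knockout arrays 2 and 3 are therefore given below with and without these arrays, a comparison chosen after the data were seen.

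**Figure D1:**
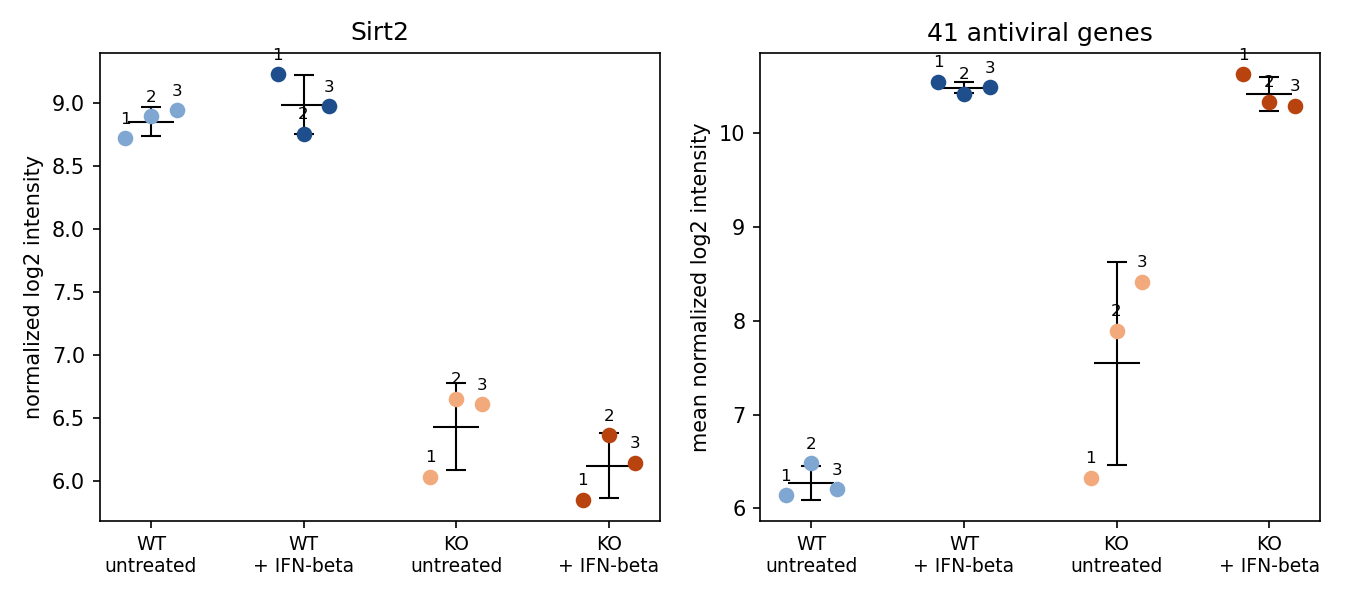
Normalized log2 intensity of Sirt2 (left) and mean normalized log2 intensity of the 41 tested antiviral genes (right) for each array, numbered by replicate. Bars give the group mean and SD, n = 3. The antiviral mean was 6.33 in untreated knockout array 1, close to the untreated wild-type arrays (6.14, 6.48 and 6.20), but 7.89 and 8.41 in arrays 2 and 3.

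**Figure D2:**
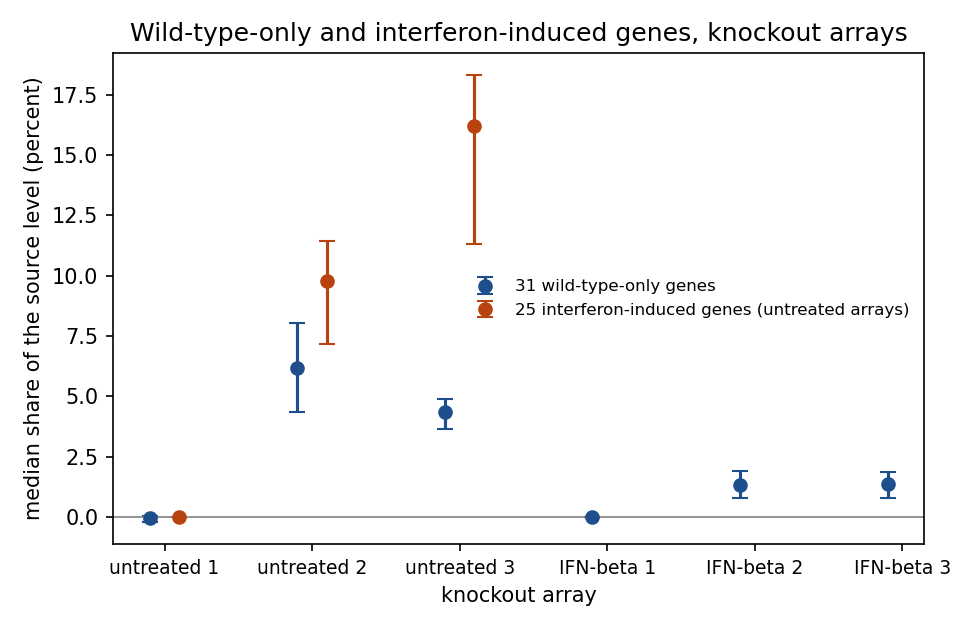
Median level of the 31 wild-type-only genes in each knockout array, in percent of the wild-type level, and of the 25 interferon-induced genes in the untreated knockout arrays, in percent of the treated level. Bars are 95% bootstrap intervals over genes. Treated array 1 is the zero of the first set and untreated array 1 that of the second, so those points are 0 by construction.

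In wild-type fibroblasts, interferon beta switched on the antiviral programme. All 41 tested antiviral interferon-stimulated genes rose, over all genes and adjusted over the list alone, with a median log2 change of 3.87. Cxcl10, a chemokine that draws T cells, rose at least 471-fold (adjusted p = 6.15e-08), and Rsad2, which encodes the antiviral enzyme viperin, at least 214-fold (adjusted p = 1.95e-05). Neither was well above background before treatment, so both folds are lower bounds. Usp18, which removes the ubiquitin-like protein ISG15 and dampens the interferon receptor, rose by 8.50 ± 1.18 on the log2 scale (SE, n = 3 per group, adjusted p = 0.000267), and Ifit3 by 8.12 ± 1.20 (adjusted p = 0.000459). In each of these genes all 3 treated arrays lay above all 3 untreated ones. The standard errors pool the spread of all 4 groups, so the unlike untreated knockout arrays enter them too. They do not measure the spread among the wild-type arrays alone.

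The comparison asks what the treatment does where Sirt2 is present. At an adjusted p under 0.05, 760 genes were higher and 917 lower under interferon, of 12128 tested. A change of at least 2-fold was seen in 344 of the higher and 12 of the lower genes. The 10 tested guanylate-binding and immunity-related GTPases all rose (10 adjusted over the list alone), by a median of 5.66. Gbp2 rose at least 308-fold (adjusted p = 1.32e-05) and Igtp by 8.23 ± 1.17 (adjusted p = 0.000332). Of 22 genes of MHC class I antigen presentation, 20 rose (20 adjusted over the list alone) with a median of 2.45. The immunoproteasome subunit Psmb9 stood at 4.32 ± 0.48 (adjusted p = 3.60e-05) and the peptide transporter Tap1 at 4.06 ± 0.44 (adjusted p = 2.52e-05). Of the components of the pathway itself, Stat2 rose by 4.26 ± 0.53 (adjusted p = 9.73e-05) and Irf9 by 3.21 ± 0.22 (adjusted p = 8.11e-07). Irf7, a factor that widens the response, rose at least 42.9-fold (adjusted p = 8.82e-06). Isg15 rose by 7.17 ± 0.59 (adjusted p = 2.67e-06), Oasl2 at least 178-fold, Mx2 at least 79.9-fold, Mx1 at least 5.80-fold and Oas1a by 2.29 ± 0.24. Chemokines and cytokines rose in 12 of 21 tested members (14 adjusted over the list alone) and fell in 1 (1 adjusted over the list alone). Genes of cholesterol synthesis and uptake fell in 3 of 16 (6 adjusted over the list alone), with a median of −0.33. The largest fall was that of Dhcr7 at −0.80 ± 0.16 (adjusted p = 0.00554). The largest falls were small beside the rises, such as −1.13 ± 0.17 for Aph1b (adjusted p = 0.000683), which encodes a subunit of gamma-secretase. Slc40a1, the iron exporter ferroportin, stood at −1.05 ± 0.13 (adjusted p = 7.22e-05). In tests of whole lists with a preset correlation, 10 of 28 lists passed in this comparison. The antiviral list had an adjusted p = 7.11e-58, and adjusted p = 0.0554 with an estimated correlation. With all arrays no list passed with an estimated correlation in any of the 5 comparisons. Without untreated knockout arrays 2 and 3 the antiviral list passed here (adjusted p = 0.012). The balance of higher and lower genes was not stable: 648 were higher and 588 lower without untreated wild-type array 1, 612 and 518 without treated wild-type array 1, and 695 and 1245 with median scaling.

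Knockout fibroblasts also turned on the antiviral genes. Of the 41 tested, 37 rose (40 adjusted over the list alone), with a median log2 change of 3.01, which was 4.28 without untreated knockout arrays 2 and 3. On the lone untreated array 15 of the 41 were not detected. With undetected values raised to the background level that second median was 4.08. Rsad2 rose by 5.38 ± 0.86 (SE, n = 3 per group, adjusted p = 0.00141; at least 233-fold without the 2 arrays), Gbp2 by 5.12 ± 0.85 (adjusted p = 0.00174; 7.78 without them) and Cxcl10 by 4.36 ± 0.47 (adjusted p = 5.57e-05; 5.96 without them). Usp18 at 3.97 ± 1.18 (adjusted p = 0.0678) and Ifit3 at 4.08 ± 1.20 (adjusted p = 0.0658) did not pass with all arrays. They stood at 8.18 and 8.37 without the 2 arrays.

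This comparison gives the same treatment where Sirt2 is deleted. It found that 522 genes were higher and 280 lower under interferon, of which 280 and 1 changed at least 2-fold. With median scaling this balance turned, to 466 higher and 886 lower. All 10 GTPases rose (10 adjusted over the list alone) with a median of 3.52 (5.63 without the 2 arrays). On the lone untreated array 7 of the 10 were not detected. With undetected values raised to the background level the median without the 2 arrays was 5.49. Of 22 antigen presentation genes, 21 rose (21 adjusted over the list alone) with a median of 2.04 (2.49 without them). Stat2 rose by 2.83 ± 0.53 (adjusted p = 0.00456; at least 18.2-fold without the 2 arrays), Irf9 by 2.80 ± 0.22 (adjusted p = 1.03e-05; 3.46), Irf7 by 3.49 ± 0.55 (adjusted p = 0.00117; at least 27.6-fold) and Isg15 by 3.30 ± 0.59 (adjusted p = 0.00316; 5.34). Mx2 rose by 4.12 ± 0.68 (adjusted p = 0.00167; at least 74.0-fold without the 2 arrays), Mx1 by 1.90 ± 0.28 (adjusted p = 0.000739) and Oas1a by 2.66 ± 0.24 (adjusted p = 1.55e-05). Oasl2 rose by 3.63 ± 0.87 (adjusted p = 0.0226; 6.67 without them). This call was lost without any of the treated knockout arrays (3.54 without array 1, 3.70 without array 2, 3.65 without array 3). Without untreated knockout array 1 the value was 2.11. Among lower genes, the growth factor-induced transcription factor Egr1 fell by 1.00 (± 0.17, adjusted p = 0.0021) and Zmat3, a target of p53, by 0.95 (± 0.15, adjusted p = 0.00131). The lower count depended on single arrays: it was 167, 143 and 174 without untreated knockout array 1, 2 or 3, and 118 without treated knockout array 1. Without untreated arrays 2 and 3 together, 409 genes were higher and 80 lower, 377 and 57 of them also called with all arrays. In tests of whole lists, 7 of 28 passed. The antiviral list had an adjusted p = 3.89e-55, and adjusted p = 0.0548 with an estimated correlation. The responses of the 2 genotypes take means of different arrays, but each gene's spread is estimated over all 12. Their calls are therefore not independent. In both, 443 genes rose, against 32.7 for independent lists, 163 fell, against 21.2, and 0 were called in opposite directions.

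Under interferon, Grb10 and Cdkn2a were among the genes with the largest higher values in the knockout, and Hoxc6 and Grem1 among those with the largest lower ones. Grb10, an imprinted gene for an adaptor of growth factor receptors, was higher in the knockout by 7.15 ± 0.38 on the log2 scale (SE, n = 3 per group, adjusted p = 1.89e-08). Cdkn2a, which encodes the cell cycle inhibitors p16 and p19ARF, was higher by 6.59 ± 0.38 (adjusted p = 3.11e-08). Its log2 level was 4.49, 6.42 and 4.42 in treated wild-type arrays 1, 2 and 3, not above background in arrays 1 and 3. It is among the 7 knockout-only genes that array 2 held, so its difference is not a precise one. Hoxc6, a homeobox gene, was at least 163-fold lower (adjusted p = 3.02e-06), and not well above background in the treated knockout. Grem1, which encodes a blocker of bone morphogenetic proteins, was lower by a log2 difference of −6.17 ± 0.45 (adjusted p = 1.88e-07). The difference of the antiviral genes as a group did not pass a test. Their mean was 10.48 ± 0.06 in wild type and 10.42 ± 0.18 in the knockout (SD, n = 3), a difference of −0.07 (exact permutation test, two-sided, p = 0.6, smallest possible 0.1).

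This comparison asks which genes differ between genotypes after treatment. In the knockout 3288 genes were higher and 2818 lower, of which 575 and 939 differed at least 2-fold. HOX genes were lower in 12 and higher in 3 of 20 tested members (12 and 3 adjusted over the list alone), with a median of −1.44 (adjusted p = 0.000722 for the list, or adjusted p = 0.22 with an estimated correlation). Extracellular matrix genes were lower in 18 and higher in 6 of 31 (18 and 7 adjusted over the list alone), with a median of −0.74 (adjusted p = 0.00184, or adjusted p = 0.285 with an estimated correlation). The collagen-binding proteoglycan Dcn stood at −4.42 ± 0.37 and the basement membrane collagen Col4a2 at −3.68 ± 0.23. Cell cycle genes were higher in 19 and lower in 2 of 28 (23 and 3 adjusted over the list alone), with a median of 0.44 (adjusted p = 0.0012, or adjusted p = 0.22 with an estimated correlation). The replication helicase subunit Mcm2 stood at 1.20 ± 0.12, while Ccnd1, which encodes cyclin D1, stood at −1.29 ± 0.11. Cholesterol genes were lower in 12 and higher in 2 of 16 (12 and 2 adjusted over the list alone), with a median of −0.61 (adjusted p = 0.004, or adjusted p = 0.171 with an estimated correlation). In the antiviral list 2 members were higher and 4 lower (0 and 3 adjusted over the list alone). Here the median (0.05), the mean (−0.07) and the list test (down, adjusted p = 0.679) differed in sign. Ifit2 was lower by a log2 difference of −1.69 ± 0.36 (adjusted p = 0.00159), Tgtp1, a GTPase induced by interferon, by −1.93 ± 0.32 (adjusted p = 0.000243) and the chemokine Ccl7 by −2.91 ± 0.67 (adjusted p = 0.00272). H2-Q6, a class I-like MHC gene, was higher by 2.35 ± 0.21 (adjusted p = 9.70e-07). Cdk9, a kinase of transcription elongation, was higher by 0.51 ± 0.13 (adjusted p = 0.00505), and by 0.48 ± 0.13 (adjusted p = 0.00715) without interferon. Among other genes fixed in advance, Stat2 at −1.19 (adjusted p = 0.0782), Irf9 at 0.56 (adjusted p = 0.0518), Oas1a at 0.60 (adjusted p = 0.0515), Mx1 at −0.58 (adjusted p = 0.101) and Cxcl10 at 0.62 (adjusted p = 0.292) did not pass. Genotype cannot be separated here from other differences between the cell populations. Xist was lower by −4.27 ± 0.55 and the Y-linked gene Eif2s3y higher by 4.30 ± 0.44 in the knockout. Eif2s3y, also a knockout-only gene, was not above background in treated wild-type arrays 1 and 3 and stood at 6.78 in array 2. Dcn and Xist, both wild-type-only genes, were not above background in treated knockout array 1 (4.89 and 4.36). In treated knockout arrays 2 and 3, Dcn stood at 5.51 and 5.85 and Xist at 6.32 and 5.05. The differences of Dcn and Xist are therefore not precise either.

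**Figure D3:**
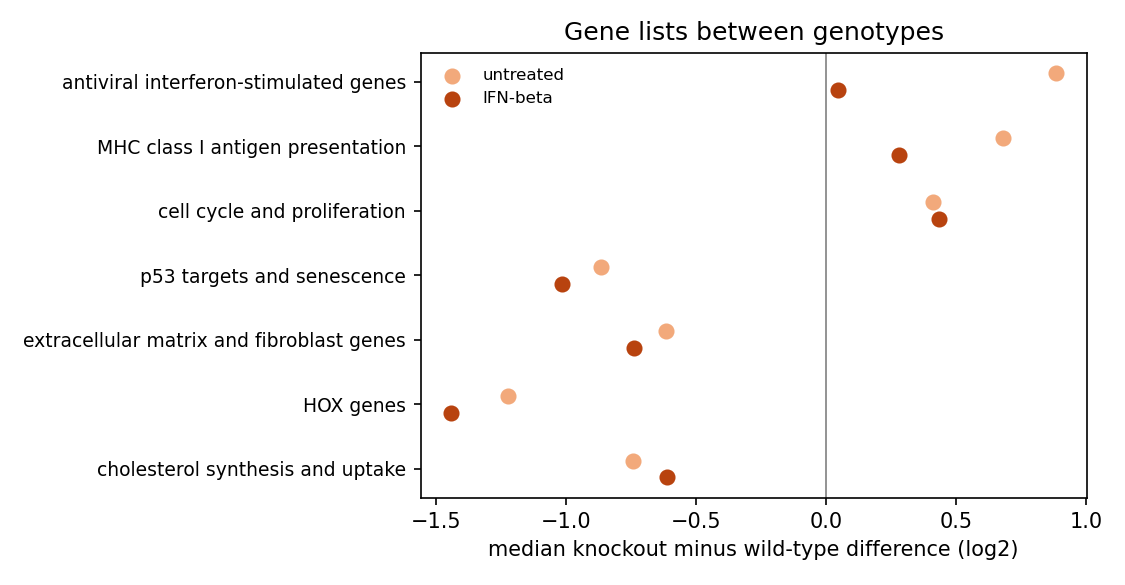
Median log2 difference between knockout and wild type over the tested members of 7 gene lists, untreated and under interferon beta. The HOX, matrix, p53 and cholesterol medians lie below 0 in both conditions and the cell cycle median above 0, while the antiviral median was 0.89 untreated and 0.05 under interferon.

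Without interferon, Grb10 and Cdkn2a were also among the genes with the largest higher values in the knockout. Grb10 was higher by 7.70 ± 0.38 (log2, SE, n = 3 per group, adjusted p = 1.10e-08), Cdkn2a at least 108-fold (adjusted p = 1.88e-08) and its neighbour Cdkn2b by 4.21 ± 0.33 (adjusted p = 3.41e-07). Cdkn1a, a p53 target that encodes p21, was lower by a log2 difference of −1.88 ± 0.16 (adjusted p = 8.70e-07). Antiviral genes were higher in 22 of 41 members and lower in 1 (23 and 1 adjusted over the list alone), with a median of 0.89. Without untreated knockout arrays 2 and 3 their median was −0.06.

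This comparison asks what differs before treatment. In the knockout 3282 genes were higher and 2935 lower, of which 588 and 940 differed at least 2-fold. Without the 2 arrays 2359 were higher and 2227 lower, 2255 and 2145 of them also called with all arrays. Of the genes called under interferon, 2627 were also higher here, against 889.8 for independent lists, and 2436 also lower, against 682. The 2 comparisons take means of different arrays, but each gene's spread is estimated over all 12. Their calls are therefore not independent. Cck and Hoxc6 were lower by −5.05 ± 0.80 and −5.20 ± 0.77, or at least 162-fold and 174-fold lower without the 2 arrays. HOX genes were lower in 12 and higher in 4 of 20 (12 and 4 adjusted over the list alone), with a median of −1.22 (adjusted p = 0.00333, or adjusted p = 0.291 with an estimated correlation). Matrix genes were lower in 20 and higher in 5 of 31 (20 and 6 adjusted over the list alone), with a median of −0.62 (adjusted p = 0.00333, or adjusted p = 0.393 with an estimated correlation). Cell cycle genes were higher in 18 and lower in 3 of 28 (18 and 3 adjusted over the list alone; adjusted p = 0.00525, or adjusted p = 0.393 with an estimated correlation), with a median of 0.41. Cholesterol genes were lower in 12 and higher in 1 of 16 (12 and 1 adjusted over the list alone; adjusted p = 0.0023, or adjusted p = 0.0812 with an estimated correlation), with a median of −0.74. Among p53 targets and senescence genes 11 were lower and 4 higher of 16 (11 and 4 adjusted over the list alone), with a median of −0.86 and a list test that did not pass (adjusted p = 0.0584). Of the antiviral genes, Isg15 was higher by 4.00 ± 0.59 (adjusted p = 8.90e-05) and kept 1.96 without the 2 arrays. Cxcl10 was at least 35.1-fold higher (log2 5.57 ± 0.47; at least 11.6-fold without them). Usp18 at 4.25 ± 1.18 moved to 0.04 without the 2 arrays, Rsad2 at 3.03 ± 0.86 to 0.30 (1.74 without array 3 alone). Mx2 at 2.43 ± 0.68 moved to 0.07, while Oasl2 at 4.41 ± 0.87 was then at least 2.13-fold higher. Ifit3 at 3.59 ± 1.20 (adjusted p = 0.0235) turned to −0.70, and Irf7 at 1.64 ± 0.55 (adjusted p = 0.0233) lost its call. Without the 2 arrays Rsad2, Mx2 and Irf7 were not well above background in either genotype, so their values then compare background. The calls of Ifit3 and Irf7 were also lost without array 2 alone (2.58 for Ifit3, 1.35 for Irf7) or array 3 alone (2.46 and 1.02), and without untreated wild-type array 1 (3.52 and 1.59). Ifit3 lost the call without untreated wild-type array 2 (3.57) and Irf7 without array 3 of that group (1.53). Without untreated knockout array 1, Ifit3 stood at 5.74 and Irf7 at 2.56. Rsad2, Mx2, Oasl2 and Irf7 were not well above background in the untreated wild type, and with all arrays were at least 5.59-fold, 4.24-fold, 17.4-fold and 2.45-fold higher in the knockout. Stat2 at 0.24 (adjusted p = 0.735) did not pass, and was at least 2.17-fold lower without the 2 arrays. Antigen presentation genes were higher in 12 and lower in 1 of 22 (14 and 1 adjusted over the list alone). Their list test gave an adjusted p = 0.0171, or adjusted p = 0.649 with an estimated correlation. Without the 2 arrays their median was 0.20, or −0.0036 with undetected values raised to the background level. The antiviral list test passed with all arrays (adjusted p = 0.0036, or adjusted p = 0.649 with an estimated correlation), while the difference of the mean over its members, 1.27, did not (exact permutation test, two-sided, p = 0.2, smallest possible 0.1).

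Cxcl10, Ccl8, Il6 and Ch25h responded less to interferon in the knockout. The response of Cxcl10 was smaller by a log2 difference of −4.95 ± 0.66 (SE, n = 3 per group, adjusted p = 0.00386). It was −3.36 without untreated knockout arrays 2 and 3. The difference of Cxcl10 from wild type under interferon did not pass (0.62, adjusted p = 0.292), while Cxcl10 was at least 35.1-fold higher untreated (at least 11.6-fold without the 2 arrays). Responses were also smaller for the chemokine Ccl8 at −2.36 ± 0.23 (adjusted p = 0.000244; −2.21 without the 2 arrays) and the cytokine Il6 at −1.76 ± 0.22 (adjusted p = 0.00244; −1.45). So was that of Ch25h, which makes the antiviral sterol 25-hydroxycholesterol, at −3.21 ± 0.51 (adjusted p = 0.0104; −2.00). Chemokines and cytokines responded less in 4 and more in 1 of 21 (5 and 1 adjusted over the list alone), with a median of −0.26 (adjusted p = 0.00023, or adjusted p = 0.212 with an estimated correlation). Without the 2 arrays the median was 0.06 and the mean −0.23, which differ in sign (adjusted p = 0.349). None of the 41 antiviral list members passed over all genes (1 larger and 12 smaller adjusted over the list alone), although the median of the list's differences was −0.997, or −0.080 without the 2 arrays.

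This comparison tests whether the response itself depends on the genotype, the subject of the study's title. At an adjusted p under 0.05, 14 genes responded more and 47 less in the knockout, of which 10 and 42 differed at least 2-fold. A total of 916 genes had an unadjusted p under 0.05. Without the 2 arrays the counts were 16 and 25, with 7 and 22 genes shared. The smaller responses numbered 154 without untreated knockout array 1 and 31 without array 2. The larger ones numbered 8 without untreated wild-type array 1, 7 without treated wild-type array 1, 7 without untreated knockout array 2 and 9 without treated knockout array 1. Interferon-inducible genes with smaller responses that held without the 2 arrays include Ifit1bl1 at −3.20 ± 0.27 (adjusted p = 9.43e-05; −2.74) and Mndal, a member of the DNA-binding Ifi200 family, at −2.47 ± 0.17 (adjusted p = 3.50e-05; −2.37). They also include Apol9b at −2.88 ± 0.32 (adjusted p = 0.000861; −2.23) and Casp4, the caspase that senses lipopolysaccharide, at −1.62 ± 0.18 (adjusted p = 0.000861; −1.39). A smaller response need not mean a lower level under interferon. The log2 level of Apol9b was 10.17 to 10.59 in the treated knockout and 10.30 to 10.61 in treated wild type. Untreated, it was 7.15 to 8.22 in the knockout and 4.92 to 5.19 in wild type. Among larger responses, Rprm at 1.46 ± 0.23 (adjusted p = 0.011; 1.74 without the 2 arrays), Cables1 at 1.30 ± 0.21 (adjusted p = 0.0105; 1.48) and the integrin gene Itgb6 at 1.11 ± 0.16 (adjusted p = 0.00539; 1.16) held. Rprm and Itgb6 were not well above background in either wild-type group, so their wild-type response was not measured. GTPases responded less in 1 of 10 (4 adjusted over the list alone), with a median of −2.19 (adjusted p = 1.30e-09, or adjusted p = 0.232 with an estimated correlation). Without the 2 arrays the median was −0.30 (adjusted p = 0.0865). The antiviral list test gave an adjusted p = 5.96e-16, or adjusted p = 0.372 with an estimated correlation, and an adjusted p = 0.272 without the 2 arrays. Of its members, Isg15 at −3.87 ± 0.83 (adjusted p = 0.0724) did not pass with all arrays, and stood at −1.83 without the 2 arrays. Oasl2 at −4.13 (adjusted p = 0.265), Usp18 at −4.53 (adjusted p = 0.477), Ifit3 at −4.04 (adjusted p = 0.574), Rsad2 at −2.91 (adjusted p = 0.574) and Mx2 at −2.55 (adjusted p = 0.499) did not pass with all arrays either. Without the 2 arrays their differences were −1.09, −0.32, 0.25, −0.18 and −0.18. Cxcl10, Casp4, Il6, Ifit1bl1, Mndal, Rprm, Itgb6, Oasl2, Rsad2 and Mx2 were not well above background in the untreated wild type, nor Ccl8 in the untreated knockout, so their differences also depend on the background estimate. So do the values without the 2 arrays of Ccl8, Ch25h, Il6, Ifit1bl1, Mndal, Casp4, Itgb6, Rsad2 and Mx2, which were not well above background in untreated knockout array 1. Over the 304 genes called at least 2-fold higher for the mean of both responses, 243 had a smaller response in the knockout. The median difference of the 304 genes was −0.58, or −0.068 without the 2 arrays, where 167 had a smaller response.

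**Figure D4:**
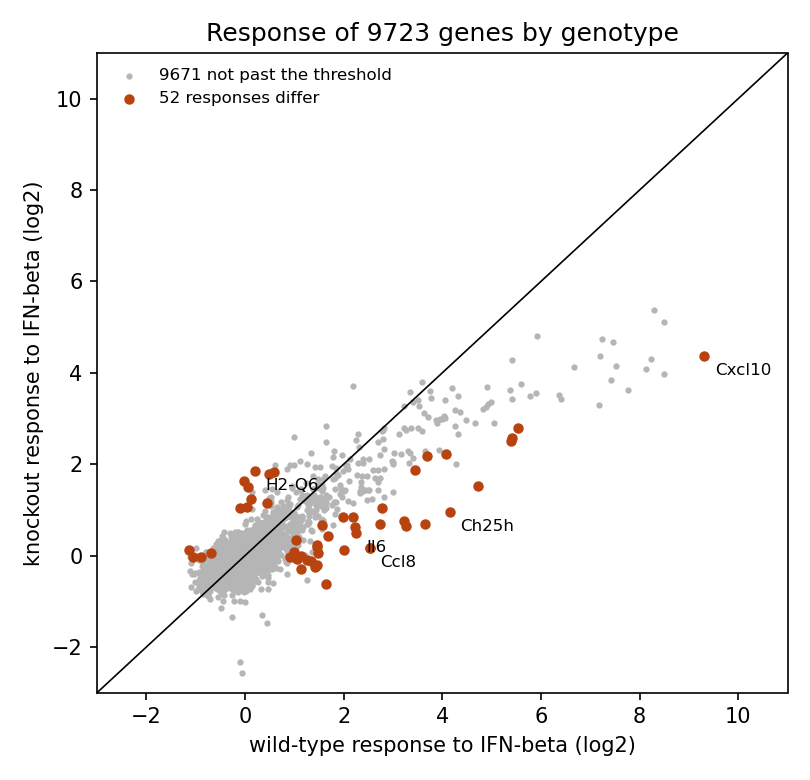
Log2 response to interferon beta in knockout against wild-type fibroblasts for 9723 named genes, with the 13 larger and 39 smaller knockout responses at an adjusted p under 0.05 in colour and the line of equal responses in black. The strongest wild-type responses lie below the line; Cxcl10 stands at 9.31 in wild type and 4.36 in the knockout with all arrays. Without untreated knockout arrays 2 and 3 the difference of Usp18 moves from −4.53 to −0.32 and that of Cxcl10 from −4.95 to −3.36. The median difference of the 344 genes called at least 2-fold higher in wild type moves from −0.64 to −0.23, a choice of genes that favours smaller knockout responses. For the 280 genes called so in the knockout, a choice that favours larger ones, it moves from −0.37 to 0.087.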

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

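All tests of explanations in this part were chosen after the results were seen, apart from the counts over other splits of the arrays as measured and the test of the difference of the responses, which were planned.

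In limma's test of the difference itself, 13 named genes had a larger and 39 a smaller response in the knockout, and the 28 that the naming rule picks are given here. Knockout minus wild type, the log2 difference was −4.95 for Cxcl10, −3.21 for Ch25h, −3.20 for Ifit1bl1, −2.95 for the chemokine-binding receptor Ccrl2, −2.88 for Apol9b, −2.84 for Tgtp1, −2.74 for Apol9a, −2.62 for Enpp4, −2.47 for Mndal, −2.36 for Pstpip1, −2.36 for Ccl8 and −2.05 for Mpeg1. It was −1.76 for Il6, −1.67 for Hoxd4, −1.62 for Casp4, −1.24 for the stress-induced factor Atf3, −1.23 for Bid and −0.90 for Nfkbiz. Despite its smaller response, the log2 level of Apol9a was higher in the knockout both untreated (7.55 to 9.11 against 5.25 to 5.46) and treated (11.09 to 11.51 against 10.76 to 10.98). Larger responses in the knockout included those of Slc40a1 at 1.01, Ccl4 at 1.01, Itgb6 at 1.11, Krt16 at 1.15, Gna14 at 1.24, Rin2 at 1.24, Cables1 at 1.30, Rprm at 1.46, H2-Q6 at 1.64 and Diras2 at 1.66. Hoxd4 and Slc40a1 were not well above background in either knockout group, nor Ccl4, Itgb6, Krt16 and Rprm in either wild-type group, so there the response of that genotype was not measured. Casp4, Cxcl10, H2-Q6, Ifit1bl1, Il6, Mndal, Mpeg1 and Tgtp1 were not well above background in the untreated wild type, nor Casp4, Ccl8, Gna14, Il6, Itgb6 and Mndal in the untreated knockout, so these differences also depend on the background estimate. Without untreated knockout arrays 2 and 3 the call was lost for Hoxd4 (−1.48), Atf3, Nfkbiz, Slc40a1, Ccl4, Krt16 and Gna14. A call lost with fewer arrays does not by itself show a smaller difference. Without untreated knockout array 2 alone or array 3 alone, the difference was −1.25 and −1.15 for Atf3 and −0.90 and −0.92 for Nfkbiz. It was 0.99 and 1.02 for Slc40a1 and 1.28 and 1.22 for Gna14. Without treated wild-type array 1 the call was lost for Atf3 (−1.12, adjusted p = 0.129), Diras2 (1.69, adjusted p = 0.0701), Gna14 (1.11, adjusted p = 0.093) and Rin2 (1.24, adjusted p = 0.129). It was also lost for H2-Q6 (1.54), Nfkbiz (−0.92) and Slc40a1 (0.95), with adjusted p = 0.0915 each. The differences themselves stayed close to those with all arrays. These 7 genes also lost the call without further single arrays.

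The mean of the antiviral genes stood above the wild-type range in untreated knockout arrays 2 and 3 and within it in array 1. With array 1 as the lone untreated knockout array, single genes differed from wild type in both directions, such as Isg15 at 1.96 and Ifit3 at −0.70. The spread of that group cannot be judged from 1 array. Transcripts of wild-type cells are a candidate source: the wild-type-only genes, which include Xist, stood at 4.35% of the wild-type level or more in both arrays. As the whole source in array 3, RNA of interferon-treated wild-type cells is argued against by the interferon-induced genes, whose share was higher by 12.4 percentage points (interval 7.13 to 16). Here levels were counted against the treated wild-type arrays alone. By that measure, simulated mixtures of a single treated wild-type array at the wild-type share of array 3 gave at most 0.282. In array 2 the gap was 2.69 points (0.112 to 6.26), and such mixtures at its own share gave up to 0.40, so there this source alone cannot be told apart from a further one. Counted against all treated arrays, a simulated mixture with 10% of treated knockout array 1 gave −0.046% by wild-type-only and 11.5% by interferon-induced genes. The shares therefore cannot tell RNA of treated knockout cells from antiviral genes raised in the untreated knockout cells themselves. Whether loss of Sirt2 raises antiviral genes without interferon cannot be told apart from chance in array 1, whose antiviral mean differed from the wild-type mean by 0.0542, since it is a lone array.

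The antiviral list had a median difference of the responses of −0.997. Its test passed with the preset correlation (adjusted p = 5.96e-16), but not with an estimated one (adjusted p = 0.372) or with fry (adjusted p = 0.336), and none of the 41 members passed over all genes. Its raised baseline in untreated knockout arrays 2 and 3 may account for this median, since the median was −0.0799 without them. A ceiling of the signal is argued against by the 29 members under a log2 value of 12 in both treated groups, whose median was −0.93 (interval −1.13 to −0.508). Of 100 splits by genotype within each treatment, drawn from 200, 3 gave as many as the 61 genes called, the real one included. That count decides nothing, since the genotype difference enters the other splits: the highest, 7650 genes, exchanges the genotypes among the treated arrays. With each gene's genotype difference subtracted, 1 of the 100 splits, the real one, gave as many and the highest other gave 2. This does not exclude chance, since the subtracted difference was estimated from the real groups. It fixes the split that exchanges the genotypes among the treated arrays at 0 genes. The repeat was also chosen after the first count was seen. An effect of untreated knockout arrays 2 and 3 is not excluded either.

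Many genes differed between the genotypes with and without interferon. A difference in sex, seen in Xist and Eif2s3y, cannot be judged as a source here. Of the named genes called without interferon, 2.83% lie on chromosomes X and Y, against 3.08% of those tested. Only 299 tested genes lie there, against 5151 called genes with a known chromosome. Most called genes therefore lie on other chromosomes whatever the source, and the share decides nothing. Differences between the cell lines or embryos other than the deletion may contribute. Of the HOX genes, which keep a record of body position, 16 of 20 differed without interferon. So did 6217 of all 12128 tested genes, so the HOX count alone says little. Differences between lines or embryos cannot be told apart from an effect of Sirt2, since the labels give no line or embryo for a sample. An effect of the deletion on these genes stays open and untested.

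For the other 4 counts of called genes, the 6 arrays of a contrast give 10 splits, too few for a share under 0.05. The real split and the highest other gave 1677 and 0 genes for the wild-type response, 802 and 7 for the knockout response, 6217 and 0 for the genotype difference without interferon, and 6106 and 0 with it. In each contrast 1 split, the real one, gave as many.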

How the results depend on the processing

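Leaving out arrays with transcripts of another group was chosen after the data were seen, and all other alternatives here were planned. Of 10834 comparisons of 445 gene values under 25 alternatives, 10301 kept direction and side of the threshold, 385 fell short of it, 140 newly passed it and 8 reversed. The causes were not tested unless given. Without untreated knockout arrays 2 and 3, which leaves fewer arrays, 80 genes were lower in the knockout response and 25 responses were smaller in the knockout, the antiviral difference was −0.080 (adjusted p = 0.272), the response size difference −0.061 (over the 322 genes then called), and 1 list was called for the difference of the responses. Without treated wild-type array 2 as well, these were 72, 21, −0.16 (adjusted p = 0.118), −0.090 and 2, and 467 genes were lower in the wild-type response. Under both, the untreated genotype difference reversed for Ifit3 (−0.70), Igtp (−0.28), Irf7 (−0.19) and Stat2 (−1.46), of which only Ifit3 was above background in the remaining knockout array, and Irf7 was so in neither genotype. Larger responses in the knockout, 14 with the chosen processing, numbered 25 without background correction, 25 with the authors' deposited values, 9 with no detection filter, 2 with detection p under 0.01 on all 12 arrays (5 smaller, against 47) and 26 with array weights (89 smaller). The lower genes of the knockout response, 280 with the chosen processing, numbered 886 with median scaling (466 higher), 176 with only the 6 arrays compared and 432 with array weights. A log2 change of at least 1 left 344 higher and 12 lower genes in the wild-type response, 280 and 1 in the knockout response, 588 and 940 in the untreated genotype difference and 575 and 939 in the treated one, by construction fewer. Leaving out single arrays gave 518 to 936 lower genes in the wild-type response, 118 to 330 in the knockout response, and 7 to 21 larger and 31 to 154 smaller responses in the knockout. With an estimated correlation 0 lists were called in each of the 5 contrasts (10, 7, 6, 4 and 5 with the preset one), and the antiviral difference of −0.997 had an adjusted p = 0.372. With fry, which tests each list on its own, 14 lists were called in the knockout response, 22 and 21 in the genotype differences without and with interferon and 0 in the difference of the responses, where the antiviral list had an adjusted p = 0.336. With a replicate block, since array numbers might pair samples, the counts were 739 and 835, 493 and 238, 3275 and 2922, 3310 and 2816, and 12 and 49, within 1.5 times the others; of 18 pairs with a number in common 4 had a residual correlation above 0.1 (−0.118 to 0.176). No scaling moved the median of all genes by over 0.1. A chip block was planned and not run, since no chip identity is given. Signal over background limits genes near the floor, whose folds are bounds.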

Other observations

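All tests in this part come from the contrasts and lists fixed in advance, and the leave-out of untreated knockout arrays 2 and 3 was chosen after the results were seen. The cell cycle inhibitors did not move together between the genotypes. Cdkn2a and Cdkn2b, which share a locus and rise as fibroblasts age in culture, were higher in the knockout under interferon by 6.59 ± 0.38 and 4.05 ± 0.33 (SE, n = 3 per group, adjusted p = 3.11e-08 and 4.37e-07). The value of Cdkn2a also depends on the background estimate, since it was not above background in treated wild-type arrays 1 and 3. Cdkn1a, a target of p53, was lower, at −2.14 ± 0.16 (adjusted p = 2.81e-07). Among the p53 targets and senescence genes, 11 were lower and 4 higher of 16 (11 and 4 adjusted over the list alone), with a median of −1.02 and a list test that did not pass (adjusted p = 0.079). Of the 7 sirtuins, Sirt3, the mitochondrial deacetylase, was lower under interferon at −0.56 ± 0.13 (adjusted p = 0.00358). In that list 3 members were lower and 1 higher (3 and 1 adjusted over the list alone; adjusted p = 0.395 for the list).

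Of 19 tested genes near Sirt2 on chromosome 7, 5 were lower and 1 higher in the knockout without interferon (5 and 1 adjusted over the list alone; adjusted p = 0.268 for the list). Zfp36, which encodes an RNA-binding protein that shortens the life of cytokine transcripts, was lower at −0.76 ± 0.15 (adjusted p = 0.000956; −1.19 without untreated knockout arrays 2 and 3). It rose with interferon in both genotypes, by 1.26 ± 0.15 in wild type (adjusted p = 7.37e-05) and 1.23 ± 0.15 in the knockout (adjusted p = 0.000164). Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, also rose in both, by 0.94 ± 0.11 (adjusted p = 7.98e-05) and 0.90 ± 0.11 (adjusted p = 0.000212). The list of cholesterol genes passed in the wild-type response with the preset correlation (adjusted p = 0.0187) and not with an estimated one (adjusted p = 0.0707), and 3 of its 16 members were lower. In the knockout response it did not pass (median −0.16, adjusted p = 0.228). The difference between the genotypes did not pass (median 0.16, adjusted p = 0.154).

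Of 10 tested reference genes, 3 were higher and 1 lower in the knockout without interferon (3 and 1 adjusted over the list alone), and the list test did not pass (adjusted p = 0.519). Of 4 tested sex-linked genes, Eif2s3y was at least 24.8-fold and Kdm5d at least 2.63-fold higher in the knockout without interferon. Xist was lower at −4.28 ± 0.55 (at least 33.9-fold lower without the 2 arrays). Other kept probes of called genes gave the opposite direction in 64 of 894 cases for the wild-type response and 22 of 414 for the knockout response. They did so in 244 of 3134 and 238 of 3054 for the genotype differences without and with interferon, and 0 of 17 for the difference of the responses.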
